A study of Danio rerio with 228 samples.

How the data were processed

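RNA was measured in pools of 10 zebrafish embryos by TempO-Seq, an assay in which pairs of detector oligonucleotides are ligated on each target RNA and sequenced, with the S1500+ panel that stands in for the transcriptome with 3183 probes. Per the labels, RNA was extracted with a Qiagen Mini kit and libraries were sequenced on a NextSeq instrument. The deposited values are counts per probe and library in 1 table, with whole numbers whose totals differ between libraries, and no normalization was found in them. fastp 0.23.2, STAR 2.7.10b and R 4.4.1 are named in the submitters' processing notes, with no role for each. The genome build, the counting step and filters are not given in the sources used here, so no coordinates are printed. Of the 3183 probes, 3060 carry a symbol found in the gene name tables used here, and 64 genes have more than 1 probe, of which the probe with the highest mean count stood for the gene. Each column was matched to its sample by the label that holds its name, and 0 columns of counts were left unused. Whether probes of near-identical paralogs share reads was not tested.

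Groups, concentrations, plate, RNA extraction batch, RNA yield and RNA integrity number came from the labels. Each chemical was compared with the DMSO pools that the labels assign to it, except PFDA. The labels of control_mixed list PFDS again where PFDA would stand, and no control label names PFDA, which was taken to belong there. The 2 DMSO pools called outliers in the labels, the 8 reference RNA and the 4 water libraries entered no comparison of the report. Water libraries held 165618 to 202586 counts and reference RNA libraries 2520942 to 4129093. No 2 pools of a group were alike within sampling noise: over 444 pairs the chi-square of counts divided by its degrees of freedom was 6.00 or more.

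Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each chemical, all 5 concentrations and the controls were fitted together with 1 mean per group, after filterByExpr and TMM scaling, by edgeR's quasi-likelihood method (glmQLFit and glmQLFTest). Tests were two-sided, p was adjusted by Benjamini-Hochberg within each contrast, and the threshold was 0.05. Genes that changed at any concentration were taken from a joint test of the 5 contrasts. Chemicals tested at the same concentration were compared directly in 9 pairs, and for PFNA, which has its own controls, as the difference of the changes from DMSO. Levels are CPM (counts scaled to the library size adjusted by TMM), as mean ± SD, and log2 changes carry the standard error of the fit. Fold changes are fitted values.

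The 33 gene lists were fixed before the data were examined and tested with camera (limma, preset correlation 0.01), adjusted over all 271 tests of lists with 5 or more members left after the low-count filter. An estimated correlation and fry were alternatives. Named genes follow a rule fixed at the same time: per chemical, the 6 largest rises and 6 largest falls among called genes with a mean count of 10 or more in either group, and for up to 4 lists with 3 or more called members the 3 members with the smallest p. For each pair, the rule takes the 3 largest differences in each direction. List members outside this rule were named after their values were seen.

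Benchmark concentrations were taken for genes past the joint test from linear, power, Hill and saturating exponential models of log2 CPM, with the model of lowest AIC and a benchmark response of 1 SD within groups. They were kept when the lack-of-fit p was over 0.1 and the value lay between a 10th of the lowest and the highest concentration. The point of departure is the 10th percentile of at least 10 kept values, with a 95% interval from the jackknife over libraries. RNA yield and integrity were compared by exact permutation tests. Scores of fish origin and background were made after the data were seen, as a library's mean position between 2 groups over the probes that differ between them.

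The steps were tested with 200 of 2707 to 2847 probes changed in each of 9 simulations of the highest concentration. Of genes changed 1.5-fold, 2-fold and 4-fold, 19.4 to 47.8%, 56.7 to 82.1% and 86.4 to 97.0% were recovered, and 1.49 to 7.32% of calls were false. In simulated pairs (2793 to 2874 probes) 8.96 to 34.3%, 41.8 to 68.7% and 81.8 to 95.5% were recovered. For 89 to 124 genes per simulation, median ratios of estimated to true benchmark concentrations were 0.973 to 1.02. Saturating fits and values below the lowest concentration had no separate test. Of 30 unchanged lists 0 passed upward, but regrouped real pools passed a median of 1 to 3.

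Alternatives were other scalings (DESeq2's size factors, total counts), no low-count filter, DESeq2's test, the replicate number, plate or extraction batch as a term, single plates, other sets of controls or of libraries in the fit, other benchmark settings and leaving out each library in turn. Others were added after the data were seen and are named as such with their values. Apical endpoints were not analysed here.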

Results

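The series measured gene expression in zebrafish embryos exposed to 1 of 9 per- and polyfluoroalkyl substances, and its title names apical and transcriptomic points of departure. Of these, only the transcriptomic side was analysed here. The chemicals were 5 perfluorinated carboxylic acids of rising chain length (PFBA, PFHxA, PFOA, PFNA and PFDA) and 4 perfluorinated sulfonic acids of rising chain length (PFBS, PFHxS, PFOS and PFDS). Embryos were exposed from 4 to 120 h post fertilisation in 0.1% DMSO at 5 concentrations of each chemical, and each library came from a pool of 10 embryos. Of 228 libraries, 26 came from DMSO pools used as controls, 2 from DMSO pools that the labels mark as left out, 8 from reference RNA and 4 from water. The rest came from exposed pools. Most exposed groups held 4 pools, each PFOS group held 5, and PFOA held 4 at 4 and 12 µM and 5 above. PFBA, PFBS, PFHxA and PFHxS shared 6 DMSO pools from Ottawa fish, called control_ottawa here. PFOA, PFOS and PFDS, and by assumption PFDA, shared 4 DMSO pools labelled as mixed fish from the Ottawa and Montreal facilities, called control_mixed. PFNA had 16 DMSO pools labelled as its controls, of which 4 shared the RNA extraction batch of the PFNA pools and 12 came from other batches and, by their names, other sets. Embryo libraries held 2254364 to 4466565 counts (median 3217205, n = 216). The labels call these pools separate replicates but do not say that they came from separate spawnings, so the p-values measure only the spread between these pools.

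The first question was which concentrations changed expression relative to DMSO. Between 2709 and 2848 probes were tested per chemical. Where a count of list members adjusted over the list alone is not given, it equalled that over all genes. At the highest concentration, PFNA at 450 µM changed 942 genes, PFOS at 40 µM changed 743, PFHxS at 400 µM changed 573, PFHxA at 600 µM changed 558 and PFDS at 6 µM changed 277. These 5 counts differed by less than 1.5 times when any 1 library of the group or its controls was left out. PFOS called 49, 53 and 120 genes at 0.4, 1.2 and 4 µM, 6.23% of the probes tested at 12 µM and 743 genes at 40 µM. PFNA called 7, 35, 120, 276 and 942 from 4 to 450 µM. PFHxS called 20, 29, 21, 218 and 573 from 6 to 400 µM. PFHxA called 15, 15, 33, 28 and 558 from 6 to 600 µM. PFDS called 0, 0 and 0 genes at 0.06, 0.2 and 0.6 µM with edgeR, where 3.47%, 5.28% and 2.47% of the probes had an unadjusted p under 0.05 and DESeq2 called 0, 0 and 0. It then called 1 gene at 2 µM and 277 at 6 µM.

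**Figure D1:**
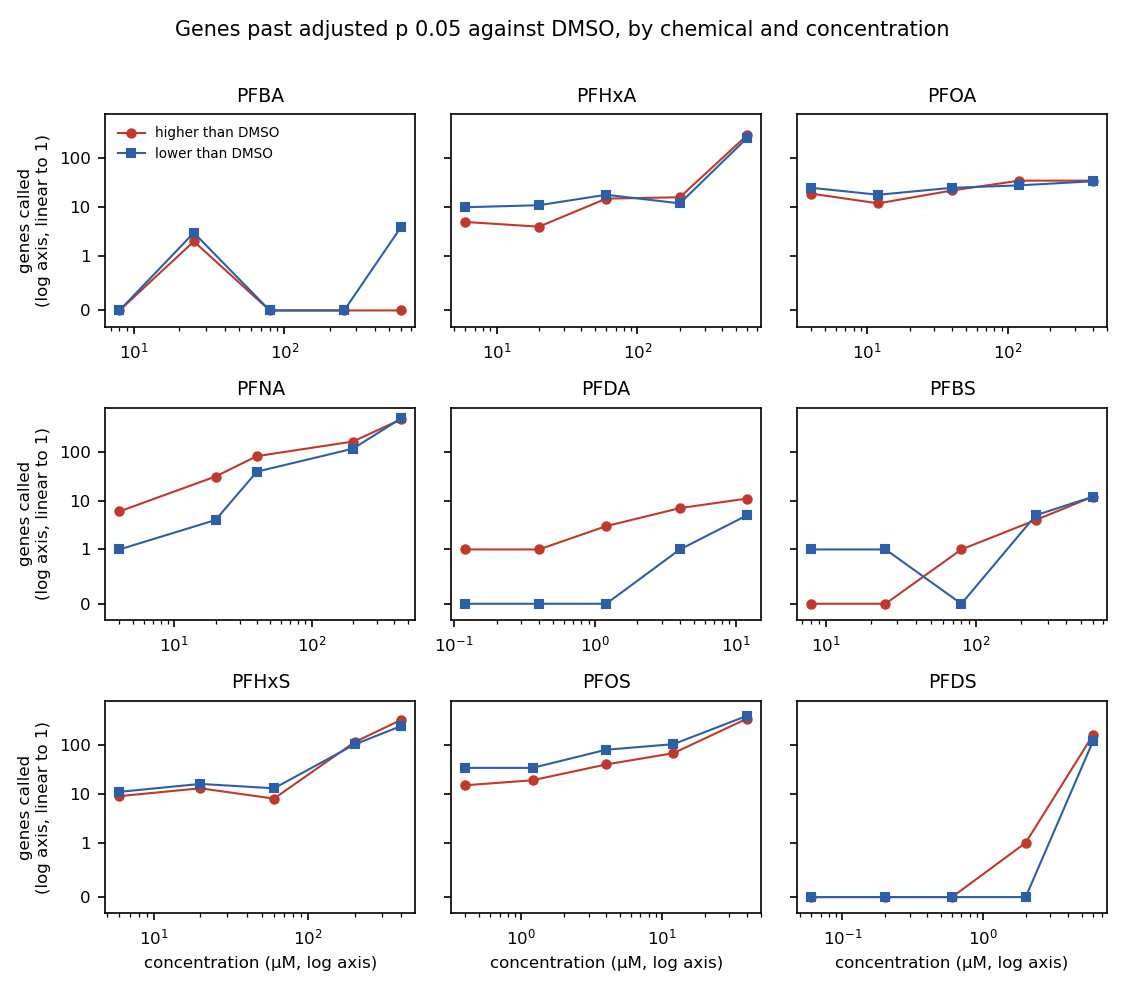
Genes past adjusted p 0.05 against DMSO (vertical log axis, linear up to 1) at each concentration in µM (horizontal log axis), with 1 panel for each of the 9 chemicals and separate lines for genes higher and lower than DMSO. PFDS goes from 1 gene at 2 µM to 277 at 6 µM, while PFOS has 49 genes at its lowest concentration.

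PFBA at 600 µM (n = 4 against 6) lowered 4 genes and raised 0 (204 genes had an unadjusted p under 0.05, and DESeq2 called 20). The vitamin D 24-hydroxylase gene cyp24a1 fell 3.1-fold, from 272 ± 100 to 87.7 ± 15.8 CPM (SD; log2 change −1.63 ± 0.23 SE, adjusted p = 0.000258), in 4 of 4 pools. The clock gene per2 (log2 change −1.17 ± 0.23), dlg3 (−0.76 ± 0.14) and the ATP synthase subunit gene atp5f1b (−0.66 ± 0.13) also fell. Of the gene lists, the cell cycle and DNA replication list was shifted upward, with a median log2 change of 0.18 over 60 genes and 0 members past the test over all genes or adjusted over the list alone (camera adjusted p = 0.000257, and adjusted p = 0.229 with an estimated correlation). The erythroid list (median 0.25, adjusted p = 0.0272, and 0.0842 with an estimated correlation) and the proteasome list (median 0.13, adjusted p = 0.0217, and 0.0514 with an estimated correlation) also shifted upward with 0 members past the test over all genes. Adjusted over the list alone, 1 erythroid gene was higher. The circadian clock list shifted downward (median −0.11, adjusted p = 0.0217) with per2 its 1 called member. Leaving out 1 library changed the count of 4 to 2 without control_ottawa replicate 1 or PFBA 600 µM replicate 1, to 1 without PFBA 600 µM replicate 2 and to 8 without control_ottawa replicate 4. The call of cyp24a1 held without each library, but ended on plate 1 alone (−1.65, adjusted p = 0.294), with both DMSO groups pooled (adjusted p = 0.337), with the left-out DMSO pools added (−1.33, adjusted p = 0.370) and against PFBA's own 8 µM pools (−0.77, adjusted p = 0.282), where edgeR called 0 genes (234 had an unadjusted p under 0.05, no other tool run). That of per2 ended without any of control_ottawa replicate 1 and PFBA 600 µM replicates 1, 2 and 3, and that of dlg3 without PFBA 600 µM replicate 2 or 3. The call of atp5f1b ended without control_ottawa replicate 1 or PFBA 600 µM replicates 1, 2 and 4 (adjusted p from 0.0544 to 0.107).

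PFHxA at 600 µM (n = 4 against 6) raised 297 genes and lowered 261. Genes of DNA replication and of immune defence were higher and genes of the clock, neurons and retina were lower. Of 59 cell cycle and DNA replication genes, 25 rose and 0 fell (30 and 1 adjusted over the list alone; median 0.61, adjusted p = 2.07e-10), among them thymidylate synthase tyms (2.55-fold, 1.35 ± 0.16) and the replicative helicase subunit mcm2 (0.71 ± 0.10). The interferon-induced GTPase gene mxc rose 10.7-fold, from 7.11 ± 4.92 to 76.4 ± 22.7 CPM (adjusted p = 1.35e-07), and the chemokine gene cxcl11.6 rose 4.34-fold. The inflammation and innate immunity list had 8 members higher and 0 lower (9 and 0 adjusted over the list alone; median 0.26, adjusted p = 0.00897, and 0.155 with an estimated correlation). Proteasome genes rose, with 7 of 20 higher and 0 lower (14 and 0 adjusted over the list alone; median 0.47, adjusted p = 2.24e-05), including the activator subunit psme1 (2.45-fold, 1.29 ± 0.16). Heat shock genes rose, with 7 higher and 0 lower (median 0.42, adjusted p = 0.000593), including hsp70.3 (2.75-fold) and hsp90aa1.2 (2.24-fold). The cholesterol biosynthesis list had 3 members higher and 1 lower (7 and 1 adjusted over the list alone; median 0.54, adjusted p = 0.0034).

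Among the falls after PFHxA at 600 µM, the circadian clock list had 6 members lower and 0 higher (9 adjusted over the list alone; median −0.58, adjusted p = 0.000131), with per2 2.93-fold lower (−1.55 ± 0.23, adjusted p = 3.27e-05), per3 at −0.99 ± 0.24 and bhlhe40 at −0.89 ± 0.17. The list of neurons, synapse and glia had 11 members lower and 0 higher (10 adjusted over the list alone; median −0.35, adjusted p = 0.00103), and the retina list 6 lower and 0 higher (7 adjusted over the list alone; median −0.41, adjusted p = 0.0018). The thyroid axis list had 4 members lower (median −0.37, adjusted p = 0.0271, and 0.0538 with an estimated correlation). These were duox, klf9, slco1c1 and thrb, named after their values were seen. The glutathione peroxidase gene gpx1a was lower by −3.60 ± 0.81 on the log2 scale and was called from 6 µM upward. Its control pools spread widely (103.4 ± 108.2 CPM) and 1 of 4 exposed pools lay beyond all controls. Its log2 change was 0.07 against the chemical's own 6 µM pools and 0.37 with a score of the pools' background as a covariate. Under scaling by total counts the split of calls was 324 higher and 180 lower (64.3% higher, against 53.2%). The count of 558 was 63 with the extraction batch as a term, where the calls of tyms, mcm2, hsp70.3, cxcl11.6, per2, per3, bhlhe40 and gpx1a ended. It was 87 against the chemical's own 6 µM pools, where those of mcm2, per2, per3, bhlhe40 and gpx1a ended, and 249 with the background score, where those of per3 and gpx1a ended.

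PFOA at 400 µM (n = 5 against 4) raised 35 genes and lowered 34. Genes of lipid synthesis and of conjugation and detoxification led the rises. The UDP-glucose dehydrogenase gene ugdh, which supplies glucuronic acid for conjugation, rose 2.82-fold, from 189 ± 27.8 to 532 ± 56.3 CPM (1.49 ± 0.12, adjusted p = 5.28e-10), and was called from 4 µM upward. The fatty acid elongase gene elovl2 rose 3.03-fold (1.6 ± 0.24, called from 12 µM), the lanosterol demethylase gene cyp51 rose 2.81-fold (1.49 ± 0.21), and the glucuronosyltransferase genes ugt2a4 (1.46 ± 0.25) and ugt2b5 (1.28 ± 0.19) rose with them. The cytochrome gene cyp2y3 rose 2.00-fold (1.00 ± 0.10, adjusted p = 3.59e-08, called from 12 µM). The list of fatty acid oxidation and PPAR targets rose, with 2 of 32 members higher and 0 lower (4 and 0 adjusted over the list alone; median 0.22, adjusted p = 0.000145), the 2 being the carnitine palmitoyltransferase genes cpt1b and cpt2. The cholesterol biosynthesis list (2 higher, 4 adjusted over the list alone; median 0.26, adjusted p = 0.000662) and the fatty acid and triglyceride synthesis list (1 of 5 higher, 2 adjusted over the list alone; median 0.44, adjusted p = 0.00618) also rose. The xenobiotic metabolism list had 3 members higher and 2 lower (10 and 4 adjusted over the list alone; median 0.19, adjusted p = 0.0321).

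Retina genes fell after PFOA at 400 µM, with 4 of 18 lower and 0 higher (6 adjusted over the list alone; median −0.38, adjusted p = 2.21e-06). The red cone opsin genes opn1lw2 (−0.81 ± 0.13) and opn1lw1 (−0.70 ± 0.12) fell in 5 of 5 pools. The apolipoprotein list (1 of 6 lower, apoea, and 2 adjusted over the list alone; median −0.32, adjusted p = 0.0221, and 0.116 with an estimated correlation) and the complement and coagulation list (1 of 16 lower, vtnb, and 3 adjusted over the list alone; median −0.20, adjusted p = 0.0324, and 0.116 with an estimated correlation) shifted downward. The Fos-family transcription factor gene fosl1a was lower by −2.46 ± 0.51 and the interferon-stimulated gene isg15 higher by 1.16 ± 0.28; the control pools of fosl1a spread widely (440 ± 420 CPM) and 1 of 5 exposed pools lay beyond all controls. The call of isg15 ended without control_mixed replicate 3 (adjusted p = 0.061) or PFOA 400 µM replicate 5 (adjusted p = 0.0612). The count of 69 was 40 without control_mixed replicate 1, 45 without control_mixed replicate 2 and 12 against the chemical's own 4 µM pools, where the calls of elovl2, cyp51, opn1lw1, opn1lw2, fosl1a and isg15 ended. Without PFOA 4 µM replicate 1, which lay far from its group, it rose from 2.17% to 3.55% of the panel's probes. Under total-count scaling 39 genes were higher and 24 lower (61.9% higher, against 50.7%).

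PFNA at 450 µM (n = 4 against 16) raised 461 genes and lowered 481, with stress and inflammation genes higher and cell division and cartilage genes lower. RNA yield and integrity were lower on average in these pools (given below), and their part in the changes was not tested. The Fos-family gene fosl1a rose 17.2-fold, from 91.5 ± 41.4 to 1576.5 ± 379.4 CPM (4.11 ± 0.23, adjusted p = 4.99e-17), and was called from 20 µM upward. The stress-response transcription factor gene atf3 rose 10.4-fold (3.38 ± 0.13, adjusted p = 9.58e-22, called from 20 µM), and trib3, a target of the integrated stress response, rose 5.45-fold (2.45 ± 0.12, called from 40 µM). Of 30 genes of the unfolded protein and integrated stress response, 14 rose and 2 fell (median 0.34, adjusted p = 1.08e-08). Heat shock genes rose (7 of 14 higher, 0 lower, adjusted p = 1.03e-06), led by hsp70.3 at 15.4-fold. The interferon regulatory factor gene irf7 rose 14.6-fold and the matrix metalloproteinase gene mmp9 rose 5.82-fold, and the inflammation list had 16 of 35 members higher and 2 lower (18 and 2 adjusted over the list alone; median 0.46, adjusted p = 1.27e-05). The p53 and apoptosis list (17 of 31 higher, 0 lower, 19 adjusted over the list alone; median 0.56, adjusted p = 1.36e-05), the NRF2 list (11 of 23 higher, 2 lower; adjusted p = 0.00704) and the circadian clock list (7 of 14 higher, 0 lower; adjusted p = 0.0079) also rose.

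Cell division genes fell after PFNA at 450 µM, with 36 of 59 lower and 0 higher (37 adjusted over the list alone; median −1.05, adjusted p = 3.28e-11). The proliferation marker mki67 fell 2.75-fold (−1.46 ± 0.18) and the mitotic genes cdc20 (−1.37 ± 0.18) and plk1 (−1.21 ± 0.16) fell with it, all from 200 µM. Cartilage, bone and matrix genes fell, with 26 of 39 lower and 0 higher (28 adjusted over the list alone; median −0.66, adjusted p = 2.79e-08). Among them the collagen genes col2a1b fell 2.07-fold (−1.05 ± 0.11) and col9a3 fell 2.24-fold (−1.17 ± 0.13, called from 40 µM). Retina genes were lower (9 of 18, 10 adjusted over the list alone; median −0.60, adjusted p = 0.0029, and 0.12 with an estimated correlation). The lists of hypoxia response (9 higher, 2 lower, and 10 and 2 adjusted over the list alone; adjusted p = 0.00389, and 0.1 with an estimated correlation), carbohydrate metabolism (13 higher, 3 lower; adjusted p = 0.028, and 0.202), cholesterol biosynthesis (8 higher, 1 lower; adjusted p = 0.0213, and 0.0861) and proteasome (7 higher, 1 lower, and 9 and 1 adjusted over the list alone; adjusted p = 0.0466, and 0.0819) shifted upward, but not with an estimated correlation. All 21 named genes kept their calls without each library in turn, and the count of 942 was 442 against the chemical's own 4 µM pools. Under total-count scaling 469 genes were higher and 450 lower (51% higher, against 48.9%).

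PFDA at 12 µM (n = 4 against 4) raised 11 genes and lowered 5. The elongase gene elovl2 rose 3.85-fold, from 39.5 ± 9.11 to 152 ± 81 CPM (1.94 ± 0.29, adjusted p = 0.000188), cyp51 rose 2.37-fold (1.245 ± 0.179), ugt2b5 rose 2.62-fold (1.39 ± 0.20) and cyp2y3 rose 1.86-fold (0.89 ± 0.12, called from 1.2 µM). These 4 calls held without each library in turn. The cholesterol biosynthesis list rose (1 of 15 higher, 3 adjusted over the list alone; median 0.31, adjusted p = 4.29e-06), as did fatty acid and triglyceride synthesis (1 of 5 higher, 2 adjusted over the list alone; median 0.22, adjusted p = 0.0036). The inflammation list shifted downward with 0 of 31 members past the test over all genes and 3 lower adjusted over the list alone (median −0.18, adjusted p = 0.00462, and 0.165 with an estimated correlation). The count of 16 was 9 without control_mixed replicate 1, 6 without control_mixed replicate 2, 9 without PFDA 12 µM replicate 1 or 2 and 10 without PFDA 12 µM replicate 3 or 4, and 6 against the chemical's own 0.12 µM pools, where the calls of elovl2, cyp51 and apoea ended. Of 12 named genes, 8 lost their calls without at least 1 library, among them the apolipoprotein gene apoea (−0.74 ± 0.16) without control_mixed replicate 1 or 2 or PFDA 12 µM replicate 1, 2 or 3 (adjusted p from 0.0648 to 0.177).

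PFBS at 600 µM (n = 4 against 6) raised 12 genes and lowered 12. Of 14 cholesterol biosynthesis genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.67, adjusted p = 9.7e-12), among them cyp51 (2.4-fold, 1.27 ± 0.22, called from 80 µM), and elovl2 rose 2.98-fold (1.57 ± 0.28). The immediate-early genes fosl1a (−2.24 ± 0.30, called from 250 µM), fosab (−1.85 ± 0.25), btg2 (−1.54 ± 0.23) and ier2b (−1.45 ± 0.24) fell, and cyp24a1 fell 4.03-fold, from 272 ± 99.9 to 67.6 ± 9.95 CPM (−2.01 ± 0.23, adjusted p = 9.31e-06), in 4 of 4 pools. These genes are among the 8 calls on background score probes (below) and kept their calls with that score as a covariate. With both DMSO groups pooled the call of cyp24a1 ended (adjusted p = 0.0849), as did those of fosl1a, btg2 and ier2b against PFBS's own 8 µM pools (adjusted p from 0.12 to 0.546). The circadian clock list shifted downward (1 of 15 lower, per2, and 4 adjusted over the list alone; median −0.31, adjusted p = 0.000593). Shifts of p53 targets (2 lower, btg2 and ddb2, and 3 adjusted over the list alone; median −0.15, adjusted p = 0.0026, and 0.0709 with an estimated correlation), inflammation (1 lower, ptgs2b, and 3 adjusted over the list alone; median −0.14, adjusted p = 0.0272, and 0.174) and neurons (1 lower, fosab; median −0.10, adjusted p = 0.00454, and 0.134) were downward. The cell cycle list was upward with 0 members past the test (median 0.14, adjusted p = 0.0219, and 0.429 with an estimated correlation). The call of ptgs2b ended without control_ottawa replicate 4 or 6 or PFBS 600 µM replicate 2, 3 or 4 (adjusted p from 0.0587 to 0.135). The count of 24 was 12, 15 and 13 without PFBS 600 µM replicates 2, 3 and 4 in turn, and under total-count scaling 10 genes were higher and 18 lower (35.7% higher, against 50%).

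PFHxS at 400 µM (n = 4 against 6) raised 328 genes and lowered 245, with glycolysis and stress genes higher and cell division genes lower. The sarcomere gene tcap rose 19.2-fold (4.26 ± 0.42, adjusted p = 3.99e-08), with a wide spread between exposed pools (1071.4 ± 1169.8 against 55.8 ± 14.2 CPM). The aldolase gene aldoaa rose 4.16-fold, from 1589.3 ± 150.02 to 6610.5 ± 1905.3 CPM (2.06 ± 0.13, adjusted p = 4.94e-12). Of 22 carbohydrate metabolism genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.49, adjusted p = 1.48e-07). Of 30 genes of the unfolded protein and integrated stress response, 14 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.64, adjusted p = 1.36e-07), including the endoplasmic reticulum chaperone hspa5 (2.43-fold, 1.28 ± 0.13), trib3 (1.31 ± 0.14) and atf3 (1.63 ± 0.19), all from 200 µM. Heat shock (6 of 14 higher, 1 lower, 8 and 1 adjusted over the list alone; median 0.95, adjusted p = 0.000257), inflammation (14 of 32 higher, 0 lower, 15 and 1 adjusted over the list alone; median 0.58, adjusted p = 3.09e-05), hypoxia response (8 of 20 higher, 1 lower; median 0.49, adjusted p = 0.0029) and proteasome genes (8 of 20 higher, 0 lower, 9 and 0 adjusted over the list alone; median 0.40, adjusted p = 0.00331) also rose, with hsp70l at 8.40-fold and irf7 at 9.87-fold. The p53 list (11 of 31 higher, 2 lower, 12 and 2 adjusted over the list alone; adjusted p = 0.0473, and 0.122 with an estimated correlation) shifted upward.

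Cell division genes fell after PFHxS at 400 µM, with 36 of 56 lower and 0 higher (40 adjusted over the list alone; median −1.06, adjusted p = 5.63e-21), including thymidine kinase tk1 (2.92-fold lower, −1.55 ± 0.20) and the microtubule regulator stmn1a (−1.45 ± 0.19), both from 200 µM. The recombination repair gene rad54l fell 3.29-fold (−1.72 ± 0.22, adjusted p = 1.9e-06). Retina genes were lower (6 lower, 0 higher; median −0.41, adjusted p = 0.00103), and 8 of 37 cartilage, bone and matrix genes were lower (median −0.29, adjusted p = 0.00952, and 0.138 with an estimated correlation). Under total-count scaling 391 genes were higher and 207 lower (65.4% higher, against 57.2%). The count of 573 was 255 with the extraction batch as a term and 260 with the lower concentrations left out of the fit. Of 23 named genes, 22 kept their calls without each library, and the fall of sprb (−1.85 ± 0.65) ended without control_ottawa replicate 1, 3, 5 or 6 or PFHxS 400 µM replicate 2, 3 or 4 (adjusted p from 0.0566 to 0.128).

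PFOS at 40 µM (n = 5 against 4) raised 347 genes and lowered 396. Heat shock, glycolysis and inflammation genes rose and cell division genes fell. The inducible chaperone gene hsp70l rose 23.4-fold, from 6.78 ± 2.34 to 160.8 ± 104.98 CPM (4.55 ± 0.41, adjusted p = 1.9e-09), hsp70.3 rose 15.7-fold and hsp90aa1.2 rose 6.69-fold (2.74 ± 0.19, called from 1.2 µM). Of 14 heat shock genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.35, adjusted p = 0.000257). The aldolase gene aldoaa rose 4.21-fold (2.07 ± 0.14, called from 12 µM) and the hexokinase gene hk1 rose 2.66-fold (1.41 ± 0.16), and carbohydrate metabolism genes rose as a list (14 of 22 higher, 1 lower; median 0.59, adjusted p = 2.39e-06), as did hypoxia response (10 of 20 higher, 1 lower; median 0.61, adjusted p = 0.000544) and the unfolded protein and integrated stress response (11 of 30 higher, 0 lower; median 0.32, adjusted p = 0.00291). The inflammation list had 16 of 34 members higher and 2 lower (median 0.56, adjusted p = 0.000436, and 0.0794 with an estimated correlation), with the cytokine gene il11a 16.6-fold higher (no call with the fish origin score as a covariate) and the signalling gene stat3 2.80-fold higher (1.49 ± 0.19). Of 56 cell cycle genes, 34 fell and 0 rose (37 adjusted over the list alone; median −0.85, adjusted p = 1.38e-13), with the replication factor gene rfc2 2.78-fold lower (−1.47 ± 0.19), from 12 µM. The retina list shifted downward (6 lower, 1 higher; median −0.32, adjusted p = 0.0406, and 0.241 with an estimated correlation).

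The 6 largest falls after PFOS at 40 µM were of another kind. They were oclna (−5.93 ± 0.83), tm9sf3 (−5.72 ± 0.75), mdm2 (−5.72 ± 0.78), zgc:103700 (−5.32 ± 1.16), fn1a (−5.21 ± 0.73) and mhc1uba (−4.995 ± 0.80). Each was near the floor in the exposed pools, and control_ottawa pools were also low: tm9sf3 was at 1.83 ± 0.657 CPM in PFOS at 40 µM, and with the DMSO pools scaled together it was at 97.2 ± 34.5 CPM in control_mixed and 2.51 ± 0.946 in control_ottawa. Against control_ottawa, mdm2 had a log2 change of 0.10 (adjusted p = 0.954) and tm9sf3 one of −0.47 (adjusted p = 0.738). In all, 85 of the 743 calls lay among the probes that differed between control_mixed and control_ottawa, 91 of them higher and 31 lower in control_mixed. The count of 743 was 610 against control_ottawa. Under total-count scaling 369 genes were higher and 303 lower (54.9% higher, against 46.7%). With a score over the probes that differed as a covariate, it fell from 23.3% to 4.18% of the panel's probes.

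PFDS at 6 µM (n = 4 against 4) changed 277 genes, 57.4% of them upward. Muscle, glycolysis and inflammation genes rose and cell division genes fell. The sarcomere gene tcap rose 10.25-fold, from 94.2 ± 9.71 to 966 ± 280 CPM (3.36 ± 0.24, adjusted p = 4.95e-10), and was the 1 gene called at 2 µM. Muscle genes rose as a list (4 of 14 higher, 0 lower; median 0.24, adjusted p = 0.00129), the others being acta1a, desma and pygma. The aldolase gene aldoaa rose 4.37-fold (2.13 ± 0.16, adjusted p = 1.66e-09), and 8 of 22 carbohydrate metabolism genes rose and 1 fell (10 and 1 adjusted over the list alone; median 0.42, adjusted p = 1.45e-05). The cytokine gene il11a rose 9.23-fold from a mean of 2 counts (called neither with DESeq2 nor on a single plate), irf7 rose 4.59-fold and stat3 rose 2.03-fold, and the inflammation list had 8 of 32 members higher and 0 lower (10 adjusted over the list alone; median 0.40, adjusted p = 6.93e-05, and 0.174 with an estimated correlation). The vitamin D hydroxylase gene cyp24a1 rose 4.59-fold (2.2 ± 0.44), but its call ended with both DMSO groups pooled (0.79, adjusted p = 0.231), its means being 73.5 CPM in control_mixed and 278 in control_ottawa. Of 55 cell cycle genes, 24 fell and 0 rose (37 adjusted over the list alone; median −0.85, adjusted p = 2.85e-19), including the spindle checkpoint gene mad2l1 (2.59-fold lower, −1.38 ± 0.16) and the spindle gene aspm (3.14-fold lower, −1.65 ± 0.28).

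Further lists shifted upward after PFDS at 6 µM, but not with an estimated correlation. These were p53 targets (6 of 32 higher, 7 adjusted over the list alone; median 0.30, adjusted p = 0.000517, and 0.186 with an estimated correlation), with btg2 (1.24 ± 0.25) and mcl1a (0.94 ± 0.19), the unfolded protein and integrated stress response (8 of 30 higher, 10 adjusted over the list alone; adjusted p = 0.0018, and 0.0842), heat shock (5 of 14 higher, 1 lower, 6 and 1 adjusted over the list alone; adjusted p = 0.0329, and 0.111), hypoxia response (4 of 19 higher, 8 adjusted over the list alone; adjusted p = 0.00427, and 0.134), neurons (6 of 55 higher; adjusted p = 0.0246, and 0.212) and the mitochondrial respiratory chain (3 of 17 higher, cyc1, uqcrc1 and slc25a4, and 5 adjusted over the list alone; adjusted p = 0.0034, and 0.193). The intestinal epithelium list shifted downward (2 of 18 lower, slc2a5 and aqp3a, and 5 adjusted over the list alone; median −0.26, adjusted p = 0.0187, and 0.134 with an estimated correlation). The call of slc2a5 ended without control_mixed replicate 2, 3 or 4 or any 1 of the 4 PFDS pools (adjusted p from 0.051 to 0.087). Under total-count scaling 187 genes were higher and 84 lower (69% higher, against 57.4%). Among plate 1 pools alone, which leave 1 control pool, edgeR called 0 genes.

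Across the 33 gene lists and 9 chemicals, 70 of 271 list tests passed with a preset correlation and 41 with an estimated one. The median, mean and test differed in sign in 35 tests, of which 0 passed. The cell cycle and DNA replication list passed for 7 chemicals, and its direction differed between them: it fell with PFNA, PFHxS, PFOS and PFDS and rose with PFHxA, with smaller upward shifts for PFBA and PFBS. Cholesterol biosynthesis rose with PFHxA, PFOA, PFNA, PFDA and PFBS. Carbohydrate metabolism, hypoxia response and the unfolded protein and integrated stress response passed upward with PFNA, PFHxS, PFOS and PFDS. With an estimated correlation the cell cycle list did not pass for PFBA and PFBS, nor cholesterol biosynthesis (adjusted p = 0.0861) and carbohydrate metabolism (0.202) for PFNA, hypoxia response for PFNA (0.1) and PFDS (0.134) or the stress response list for PFDS (0.0842). Bile acid and sterol catabolism (lowest adjusted p = 0.0777, PFOA), steroid and estrogen signalling (0.159, PFHxA), endocrine pancreas (0.209, PFNA), hepatocyte (0.33, PFBA), metal handling (0.498, PFBS) and epidermis (0.114, PFOS) passed for 0 chemicals. The exocrine pancreas list had 5 tested members with PFNA alone (adjusted p = 0.634); of 4 members, 3 were lower with PFHxA (4 adjusted over the list alone; median −1.48), 3 with PFHxS (4; −0.96) and 2 with PFOS. The panel measured 0 of the lens list and 3 of the ionocyte list, which were not tested.

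**Figure D2:**
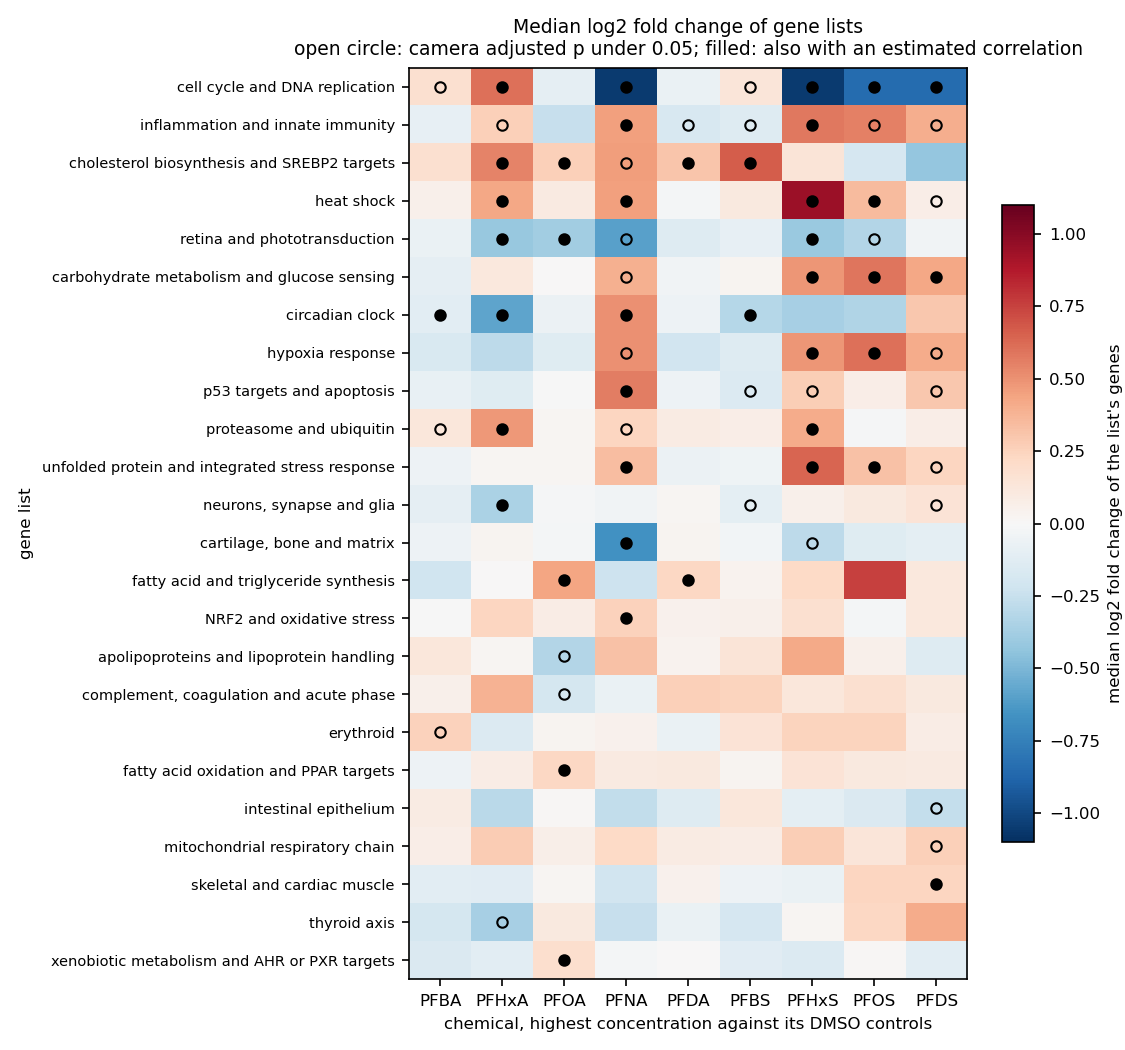
Median log2 fold change of each gene list (vertical axis) at the highest concentration of each of the 9 chemicals against DMSO (horizontal axis), on a colour scale from lower (blue) to higher (red), with open circles for camera adjusted p under 0.05 and filled circles where this also held with an estimated correlation. The cell cycle list has a median of −1.06 with PFHxS and 0.61 with PFHxA.

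The next comparisons asked whether a carboxylic and a sulfonic acid of the same carbon number acted differently at the same concentration. PFBA and PFBS at 600 µM differed in 0 genes with edgeR (93 had an unadjusted p under 0.05, DESeq2 called 3, and the median 95% interval of a gene's log2 difference was 0.993 wide), and in 15 as a difference of changes from each chemical's own 8 µM pools. At 8, 25, 80 and 250 µM, 89, 85, 182 and 97 genes differed. PFHxA and PFHxS at 200 µM differed in 456 genes, 239 higher and 217 lower with PFHxA. Between 110 and 209 genes differed at 6, 20 and 60 µM. The DNA repair gene mgmt was at 27 ± 10.0 CPM with PFHxA and 1.69 ± 0.298 with PFHxS (log2 difference 3.96 ± 0.61, adjusted p = 9.32e-06). The genes gpx1a (−4.41 ± 0.78) and bzw1b (−3.24 ± 0.63) were lower with PFHxA. As a difference of changes from each chemical's own lowest concentration, 20 genes differed at 200 µM and the calls of these 3 ended. PFOA and PFOS at 40 µM differed in 1007 genes, 531 higher and 476 lower with PFOA (52.7% higher, and 43.9% under total-count scaling, with 429 higher and 548 lower). The heat shock gene hsp70l was at 4.10 ± 1.13 CPM with PFOA and 162.02 ± 106.8 with PFOS (−5.30 ± 0.42, adjusted p = 3.3e-14). The 3 genes highest in PFOA were oclna (6.00 ± 0.67), tm9sf3 (5.99 ± 0.60) and mdm2 (5.95 ± 0.67), which also differed between the DMSO groups. The count of 1007 was 595 as a difference of changes from each chemical's own lowest concentration.

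Chain length was compared within the carboxylic acids. PFBA and PFHxA at 600 µM differed in 305 genes, 46.2% of them higher with PFBA, and in 21 as a difference of changes from their own lowest concentrations. The replication gene cdc45 was at 0.409 ± 0.206 CPM with PFBA and 4.31 ± 2.44 with PFHxA (−3.35 ± 0.82, adjusted p = 0.00551; no call with the extraction batch as a term). Under total-count scaling 74 were higher and 263 lower (22% higher), where the median log2 difference of all genes was −0.12. PFOA and PFDA at 12 µM differed in 10 genes, with the intestinal alkaline phosphatase gene alpi.2 at 124.2 ± 9.43 and 57.9 ± 6.54 CPM (1.099 ± 0.140, adjusted p = 1.75e-06) and the immediate-early genes btg2 (−1.43 ± 0.23) and fosab (−1.42 ± 0.21) lower with PFOA. That count was 6 and 4 without PFDA 12 µM replicates 3 and 4 in turn and 17 with the extraction batch as a term. As a difference of changes from the lowest concentrations it was 2, and the calls of these 3 ended. The median 95% interval was 0.922 wide. PFOS and PFDA, which differ in both chain length and head group, differed in 380 genes at 12 µM (250 without PFDA 12 µM replicate 3 and 217 without replicate 4). With the extraction batch as a term the count was 62, and as a difference of changes from the lowest concentrations it was 3, with neither per2 nor egr3 among them. The clock gene per2 was at 26.8 ± 10.7 CPM with PFOS and 223 ± 14.5 with PFDA (−3.04 ± 0.40, adjusted p = 6.88e-07, and 0.06 as that difference of changes). The immediate-early gene egr3 was lower with PFOS by −2.76 ± 0.56.

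PFNA had its own controls and processing batch, so each difference was taken between changes from DMSO. PFNA and PFOA at 40 µM differed in 77 genes, 56 with the larger change upward in PFNA and 21 in PFOA. The elongase gene elovl2 differed by −1.55 ± 0.34 (adjusted p = 0.00355), with 33.8 ± 7.72 CPM in PFNA and 119 ± 25.1 in PFOA. The largest upward difference, of fosl1a (4.27 ± 0.55), came with a control_mixed mean of 431 CPM. The count of 77 was 45 without PFNA 40 µM replicate 2 and 46, 47 and 49 without PFOA 40 µM replicates 2, 4 and 5. With the extraction batch as a term it was 50 and the call of elovl2 ended. PFNA and PFHxA at 200 µM differed in 182 genes, 68 of them with the larger change upward in PFHxA. Without PFHxA 200 µM replicate 1 the count fell from 5.72% to 3.64% of the panel's probes, and with the extraction batch as a term it was 15. The glucocorticoid-responsive gene fkbp5 was at 344.9 ± 37.05 CPM with PFNA and 115.8 ± 63.5 with PFHxA (2.51 ± 0.46, adjusted p = 0.00021). PFNA and PFDA at 4 µM differed in 3 genes, fosl1a (2.52 ± 0.55), cyp24a1 (2.404 ± 0.517) and bcat1 (0.82 ± 0.17), each with adjusted p = 0.0261, and the median 95% interval was 1.27 wide. That count was 0 without PFNA 4 µM replicate 1 or PFDA 4 µM replicate 1, 2 or 4, 1 without PFNA 4 µM replicate 3, 7 without PFNA 4 µM replicate 2, and 0 under total-count scaling or with the extraction batch as a term. It was 69 with the replicate number as a block and 11 with DESeq2. The call of fosl1a also ended without PFNA 4 µM replicate 4 (adjusted p = 0.0623) or PFDA 4 µM replicate 3 (adjusted p = 0.0512), and its difference was −0.49 with the extraction batch as a term.

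PFDS shared no concentration with PFOA, PFNA, PFDA or PFOS and was not compared with them directly. Overlap at the highest concentrations was taken only between chemicals that share no control pool and have over 100 calls. PFNA and PFHxS shared 343 genes in the same direction, 3.59 times the number from independent lists for genes higher in both and 3.38 times for genes lower in both. Another 8 genes went in opposite directions, against 98.8 from independent lists, and their log2 changes had r = 0.471 across genes. PFHxS and PFDS shared 187 (5.79 times for higher and 6.88 times for lower), with 2 opposite against 29. PFNA and PFDS shared 224 (4.92 and 4.39 times), with 3 opposite against 48. PFHxS and PFOS shared 310 (3.93 and 4.29 times), with 7 opposite against 76.7. PFNA and PFOS shared 323 (2.99 and 2.24 times), with 31 opposite against 124.5. For PFHxA, genes in opposite directions were at 1.959 times the number from independent lists with PFOS, 3.21 times with PFDS and 1.52 times with PFNA. With PFOS it shared 28 genes higher (38 from independent lists) and 39 lower (35.6), with PFDS 13 higher (17.6) and 6 lower (11.4), and with PFNA 82 higher (49.6) and 41 lower (45.7). Genes are not independent replicates, so no p-value is given for these overlaps.

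The transcriptomic point of departure was taken as the 10th percentile of benchmark concentrations of genes that changed at any concentration. PFDS had 196 such genes (85 without PFDS 6 µM replicate 4) and a point of departure of 1.46 µM (95% jackknife interval 0.952 to 2.23 µM), and the median of its benchmark concentrations was 2.06 µM. PFHxS had one of 23.9 µM (4.96 to 115.6 µM), PFNA one of 3.18 µM (0.546 to 18.5 µM), PFHxA one of 1.65 µM (0.313 to 8.74 µM), PFOA one of 0.509 µM (0.345 to 0.753 µM) and PFOS one of 0.227 µM (0.000496 to 103.8 µM). PFBS had one of 2.03 µM (0.00638 to 646 µM) and PFDA one of 0.0434 µM from 11 benchmark concentrations, with no interval. PFBA had too few benchmark concentrations for one. PFOS pools differed from their controls in fish origin score (below), which its value may reflect. The values for PFOA, PFOS, PFNA, PFHxA, PFDA and PFBS lie below the lowest concentration tested, as did 76.1% of PFOA's benchmark concentrations. Of its 46, 45 came from saturating models. None under a 10th of 4 µM was kept, so its interval may be too narrow. Values moved by over 1.5 times without 1 library. PFHxA went to 2.88 µM without control_ottawa replicate 1 and PFBS to 20.5 without replicate 6. PFHxS went to 13.7 µM without PFHxS 400 µM replicate 4, and PFOS to 2.79 and 0.124 µM without control_mixed replicates 4 and 3. PFDA had a value in only 4 of 24 refits. It went to 0.0146, 0.0248 and 0.0266 µM without control_mixed replicates 3 and 4 and PFDA 1.2 µM replicate 2. With both DMSO groups pooled the values were 2.67 µM for PFHxS, 0.575 µM for PFDS and 0.0207 µM for PFDA. Other settings moved PFHxS to 5.39 and 3.85 µM and PFNA to 10.8 and 0.948 µM (below).

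**Figure D3:**
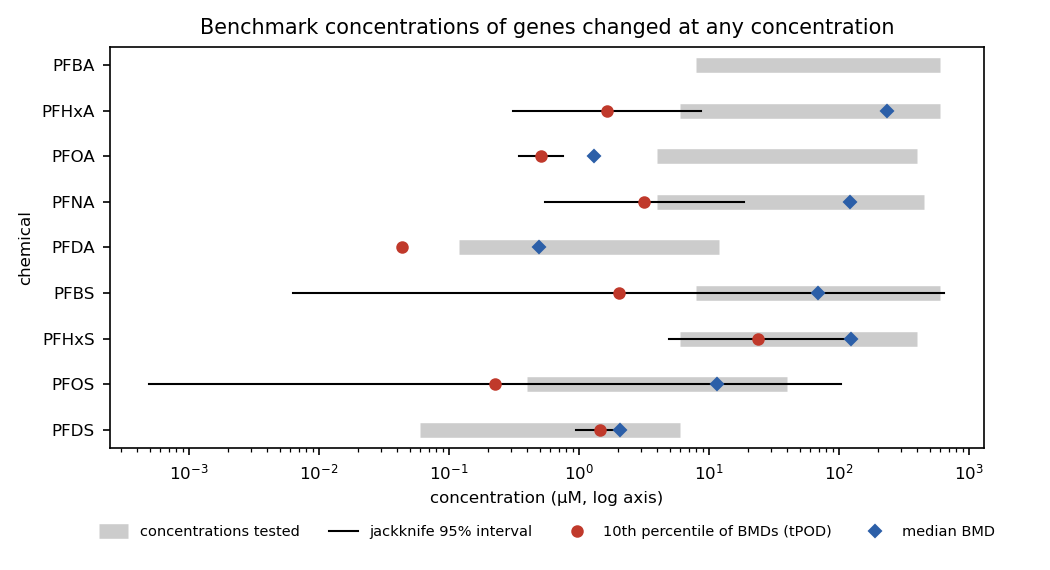
For each chemical (vertical axis), the concentrations tested (grey bar), the 10th percentile of benchmark concentrations with its jackknife 95% interval (red point and black line) and their median (blue diamond), in µM on a log axis. The interval of PFDS spans 0.952 to 2.23 µM.

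By a second description, the lowest concentration from which every higher one had 20 or more calls, the values were 0.4 µM for PFOS, 4 µM for PFOA, 6 µM for PFHxS and PFDS, 20 µM for PFNA, 60 µM for PFHxA and 600 µM for PFBS, with none for PFBA and PFDA. Under alternatives they ranged from 0.4 to 40 µM for PFOS (12 µM with the fish origin score), 4 to 120 µM for PFOA, 6 to 200 µM for PFHxS (20 µM with either other scaling), 4 to 40 µM for PFNA, 6 to 600 µM for PFHxA and 80 to 600 µM for PFBS. No concentration qualified for PFOA or PFDS on plate 1 alone, nor for PFBS there, with the replicate block, with the extraction batch as a term or without control_ottawa replicate 1 or 4 or PFBS 600 µM replicate 2, 3 or 4. RNA yield and integrity were compared at the highest concentration with exact permutation tests, two-sided, over 9 chemicals each and adjusted within each measure. PFNA pools yielded 176.8 ± 38.2 ng/µl against 250 ± 51.1 in their controls (n = 4 and 16, exact p = 0.0151, adjusted p = 0.0857), and their RNA integrity number differed by −0.313 (9.38 against 9.69, exact p = 0.00826, adjusted p = 0.0743). PFBA pools yielded 230 ± 37.8 against 287 ± 13.4 ng/µl (n = 4 and 6, exact p = 0.019, adjusted p = 0.0857). With adjustment, 0 of the 18 differences passed. Without control_ottawa replicate 3 the integrity differences of PFBA (0.425), PFHxA (0.3) and PFBS (0.325) passed, as did that of PFNA without control_pfna replicate 9 (−0.332) or PFNA 450 µM replicate 3 (−0.388), by exact permutation tests.

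A score over the probes that differed between the DMSO groups placed control_ottawa at 0 and control_mixed at 1 by construction. Groups of PFOA, PFDA and PFDS had means of 0.907 to 1.13. PFOS groups had means of 0.435 to 0.603 from 0.4 to 12 µM and of 0.075 at 40 µM, although the labels give these pools mixed fish. A further score over the 89 probes that differed between PFBA and PFBS at 8 µM (PFBS at 0, PFBA at 1) ranged from 0.042 to 1.02 over the 6 control_ottawa pools, and had group means of 0.89 to 0.993 with PFHxA, 0.54 with PFBA at 600 µM and 0.535 with PFBS at 600 µM.

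**Figure D4:**
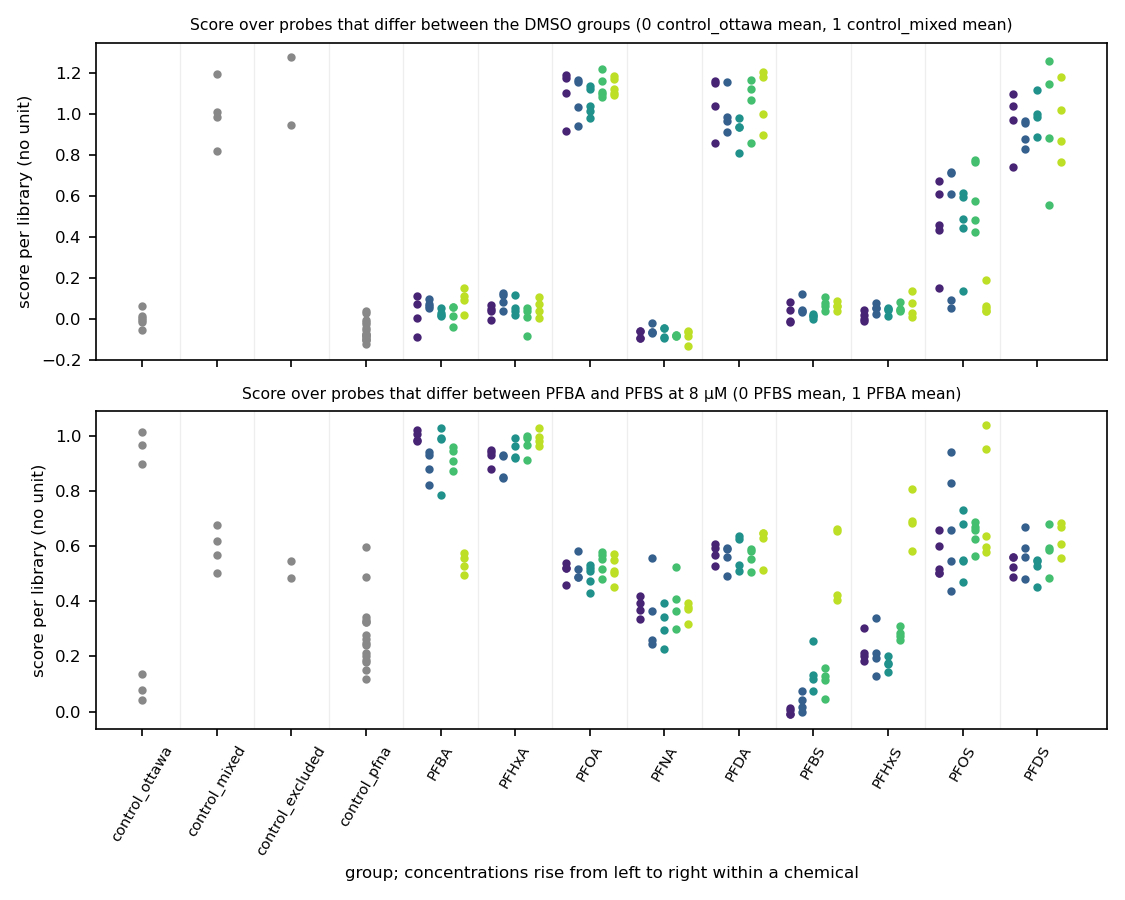
Score of each library without unit (vertical axes) by group, with concentrations rising from left to right within a chemical (horizontal axis); the upper panel is the score over probes that differ between the DMSO groups and the lower panel the score over probes that differ between PFBA and PFBS at 8 µM. PFOS pools at 40 µM have a mean of 0.075 in the upper panel.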

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

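Chosen after the results were seen were the tests of PFOS calls kept against Ottawa controls, of the spread of the background score, of PFBA against PFBS at 600 µM and of PFHxA with the background score, as were both scores; the other tests below were written down before their values were seen.

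The first pattern is that PFOS pools at 40 µM, labelled as mixed fish, resembled Ottawa fish. A score over the probes that differ between the DMSO groups is 0 at the mean of control_ottawa and 1 at the mean of control_mixed, and averaged 0.075 ± 0.063 (SD, n = 5) in these pools. For the 658 calls among the other probes, Ottawa origin as the whole cause is argued against, since 60.5% kept call and direction against control_ottawa, although all calls at 40 µM fell from 23.3% to 4.18% of the panel's probes with the score as a covariate, so a part stays open. Of these calls, 81.4% had the same sign in 12 against 0.4 µM as in 40 µM against control_ottawa, contrasts with no library in common, which is consistent with a response to PFOS. For the 85 calls among the probes that differ between the DMSO groups, origin and exposure cannot be told apart: 24.6% of these probes were called against control_ottawa, 2.60 percentage points more than of the other probes, a gap that lies between what origin (0 or less) and a response (over 15) would give.

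The second pattern is that 49 genes were called at 0.4 µM PFOS, the lowest concentration; at their lowest concentrations PFDA called 1 gene and PFOA 44 against the same controls. A candidate explanation is a larger share of Ottawa fish than in the controls: 83.7% of the 49 calls had the sign of control_ottawa minus the PFDS pools at 0.06 µM, libraries the PFOS contrast does not use. The origin score averaged 0.462 in these pools, with single pools from 0.147 to 0.669. A response to PFOS at this concentration was not tested apart from origin and stays open.

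The third pattern is a background that parted PFBA and PFHxA pools from PFBS and PFHxS pools at most concentrations. A score over the 89 probes that differ between PFBA and PFBS at 8 µM (0 for PFBS, 1 for PFBA) spread over 0.974 within the 6 unexposed control_ottawa pools, at 0.042, 0.08, 0.135, 0.9, 0.967 and 1.015, so part of this difference may come from a background unrelated to exposure. A head group effect that holds or grows with concentration is argued against, since 0 genes differed at 600 µM with edgeR (93 with an unadjusted p under 0.05, 3 with DESeq2); 15 differed as changes from each chemical's own 8 µM pools, so a head group effect of another form stays open. For PFHxA at 600 µM, background as the whole cause is argued against by the 39.2% of 558 calls (219) that kept call and direction with the score as a covariate, although 83 kept both against the chemical's own 6 µM pools, so a large part stays open.

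The 2 DMSO pools left out as outliers by the submitters carry the label of Ottawa fish, but 4.98% of 2753 probes differed between them and control_ottawa. Between them and control_mixed 0 probes differed with edgeR (3.92% at an unadjusted p under 0.05, no other tool run), and their origin score averaged 1.11.

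Of 442 groups of 4 to 10 pools tested for a pool far from the others, 27 had one, where chance gives about 1 in 20, or 22.1. Each value below is the gap to the nearest pool divided by the range of the group. RNA yield was lowest by 0.860 in PFBS 600 µM replicate 4 and 0.895 in PFHxS 20 µM replicate 3, and highest by 0.85 in PFBA 25 µM replicate 3, 0.929 in PFHxS 60 µM replicate 3 and 0.851 in PFOA 12 µM replicate 4. The RNA integrity number stood apart by 1, the other pools being tied, in PFBS 250 µM replicate 2, PFHxS 20 µM replicate 4 and PFHxA 60 µM replicate 4 (highest) and PFOA 4 µM replicate 2 (lowest). In control_mixed, replicate 1 was lowest for ncapg (0.831), opn1lw1 (0.849), rfc3 (0.855) and aldoaa (0.835), replicate 3 for isg15 (0.832) and gadd45bb (0.894), and replicate 4 for hk1 (0.876) and dbf4 (0.85), while replicate 2 was highest for hsp90aa1.2 (0.893). In control_ottawa, replicate 6 was highest for bhlhe40 (0.748). Among exposed pools, hspd1 was highest in PFHxA 600 µM replicate 3 (0.971), elovl2 in PFDA 12 µM replicate 4 (0.955), ugt2a4 in PFDA 12 µM replicate 3 (0.863) and mmp9 in PFDS 6 µM replicate 4 (0.850). LOC100004427 was lowest in PFOA 400 µM replicate 5 (0.790), trib3 in PFNA 450 µM replicate 3 (0.867), matn4 in PFNA 450 µM replicate 2 (0.844) and stat3 in PFDS 6 µM replicate 1 (0.834).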

How the results depend on the processing

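Most alternatives were fixed before the data were examined. Tests chosen after the results were seen were those against each chemical's own lowest concentration, against control_ottawa, with the fish origin or background score, without the probes that differ between the DMSO groups and without libraries far from their group. Of 206 values of named genes under 4928 combinations with alternatives, 4345 kept direction and call, 568 lost the call and 15 turned sign. With DESeq2's size factors 206 of 206 kept both, with total counts 196, without the low-count filter 203 and with the DESeq2 test 202. With the extraction batch as a term 63 lost the call and 2 turned sign, on plate 1 alone 99 of 170 and 1, and against the own lowest concentration 54 and 4. Total counts moved the median log2 difference of all genes from −0.00 to −0.12 for PFBA minus PFHxA. Of 271 gene list tests, 25.8% passed with the preset correlation, 15.1% with an estimated one and 39.9% with fry, which sets no list against other genes. Under either other scaling all 271 list tests kept their side. Most 1.5-fold changes of single genes went undetected in the simulations above, in which depth was not varied.

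Below, a share is the count of genes past the test as percent of the panel's 3183 probes, and shares are given where the count moved by over 1.5 times. The values with the design as fixed at the highest concentration were 0.126% for PFBA, 17.5% for PFHxA, 2.17% for PFOA, 29.6% for PFNA, 0.503% for PFDA, 0.754% for PFBS, 18% for PFHxS, 23.3% for PFOS and 8.70% for PFDS. At any concentration they were 0.157%, 8.48%, 2.04%, 21.9%, 0.440%, 1.26%, 16.5%, 19.9% and 6.16% in that order. Where an alternative leaves fewer pools (a single plate) or takes another percentile or benchmark response, its construction changes the power or the quantity itself; for the others the cause was not tested.

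With scaling by total counts, PFBA shares were 0.251% at the highest and 0.314% at any concentration. There, the lowest concentrations with calls were 600 µM for PFHxA and 20 µM for PFHxS, and the point of departure was 0.711 µM for PFOA. There, shares that differed were 0.0628% between PFBA and PFBS and 0% between PFNA and PFDA, and the overlap ratio was 5.23 for PFHxS and PFDS. With DESeq2's size factors, the lowest concentration with calls was 20 µM for PFHxS, and the share that differed was 0.0628% between PFBA and PFBS. Without the low-count filter, the lowest concentration with calls was 20 µM for PFHxS. With DESeq2, shares at the highest concentration were 0.628% for PFBA and 1.29% for PFBS, and shares at any concentration were 1.29% for PFBA, 13.7% for PFHxA, 3.14% for PFOA, 1.23% for PFDA and 4.12% for PFBS. There, the lowest concentrations with calls were 6 µM for PFHxA and 80 µM for PFBS, and shares that differed were 0.0943% between PFBA and PFBS, 0.911% between PFOA and PFDA and 0.346% between PFNA and PFDA. At an adjusted p of 0.01, the overlap ratios were 5.33 for PFNA and PFHxS, 3.77 for PFNA and PFOS, 6.53 for PFNA and PFDS, 6.84 for PFHxS and PFOS and 10.5 for PFHxS and PFDS.

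With the extraction batch as a term, shares at the highest concentration were 0.408% for PFBA, 1.98% for PFHxA, 0.314% for PFDA and 8.01% for PFHxS, and shares at any concentration were 0.314% for PFBA, 4.68% for PFHxA, 10.34% for PFHxS and 2.42% for PFDS. There, the lowest concentrations with calls were 600 µM for PFHxA and 40 µM for PFNA, and the log2 changes that turned sign were 3.64 for si:dkey-40c23.3 (PFHxA) and −0.49 for fosl1a (PFNA minus PFDA). There, shares that differed were 0.534% between PFOA and PFDA, 1.95% between PFOS and PFDA, 1.57% between PFNA and PFOA, 0.471% between PFNA and PFHxA and 0% between PFNA and PFDA. With the plate as a term, shares were 0.251% for PFBA at the highest concentration and 0.283% for PFDA at any. There, the share that differed was 0.0314% between PFBA and PFBS. On plate 1 alone, shares at the highest concentration were 0% for PFBA, 3.08% for PFHxA, 0.251% for PFOA, 0% for PFDA, 0.0943% for PFBS, 8.42% for PFOS and 0% for PFDS, and shares at any concentration were 0% for PFBA, 0.503% for PFHxA, 0% for PFOA, 0.0314% for PFDA, 0.0628% for PFBS, 7.04% for PFHxS, 5.94% for PFOS and 0.126% for PFDS. There, the lowest concentrations with calls were 600 µM for PFHxA and 200 µM for PFHxS, and the log2 change that turned sign was 0.059 for LOC100004427 (PFOA). There, shares that differed were 5.03% between PFHxA and PFHxS, 13.8% between PFOA and PFOS, 0.880% between PFBA and PFHxA, 0.0628% between PFOA and PFDA and 5.59% between PFOS and PFDA. On plate 2 alone, shares at the highest concentration were 0.471% for PFBA, 7.23% for PFHxA, 0.283% for PFDA and 14.2% for PFOS, and shares at any concentration were 1.85% for PFBA, 2.45% for PFHxA, 1.26% for PFOA, 0.440% for PFBS, 5.69% for PFOS and 1.89% for PFDS. There, the lowest concentrations with calls were 6 µM for PFHxA, 40 µM for PFOA and 40 µM for PFOS, and shares that differed were 6.00% between PFHxA and PFHxS, 2.702% between PFBA and PFHxA, 0.0628% between PFOA and PFDA and 1.67% between PFOS and PFDA.

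With the highest concentration and controls only, shares at the highest concentration were 0.220% for PFDA and 8.17% for PFHxS. With control_mixed and control_ottawa pooled, shares at any concentration were 1.19% for PFBA, 9.90% for PFOA, 1.41% for PFDA and 3.24% for PFBS, and shares at the highest concentration were 11.3% for PFOA, 1.602% for PFDA and 15.4% for PFDS. There, points of departure were 0.755 µM for PFOA, 0.0207 µM for PFDA, 2.67 µM for PFHxS and 0.575 µM for PFDS, and the lowest concentration with calls was 80 µM for PFBS. With the 2 left-out DMSO pools added, PFBA shares were 0.220% at the highest and 0.346% at any concentration. There, PFHxS had a lowest concentration with calls of 20 µM and a point of departure of 5.39 µM. With all of processing batch A in 1 fit, shares at the highest concentration were 0.0628% for PFBA and 1.23% for PFBS, and the lowest concentrations with calls were 6 µM for PFHxA and 80 µM for PFBS. With only the controls of extraction batch 14, the point of departure was 10.8 µM for PFNA.

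With 1 SD of the controls as the benchmark response, points of departure were 0.778 µM for PFOA and 1.03 µM for PFDS. With 2 SD they were 6.71 µM for PFHxA, 1.34 for PFOA, 37.4 for PFNA, 81.6 for PFHxS and 2.87 µM for PFDS. Taking the 25th lowest benchmark concentration, they were 1.47 µM for PFOA and 4.04 µM for PFHxS. Taking the median benchmark concentration, points of departure were 232.9 µM for PFHxA, 1.31 µM for PFOA, 120.9 µM for PFNA, 0.498 µM for PFDA, 69.4 µM for PFBS, 124.6 µM for PFHxS, 11.6 µM for PFOS and 2.06 µM for PFDS. PFHxS had 3.85 µM without the lack-of-fit filter. Asking for 10 or more calls, the lowest concentration with calls was 6 µM for PFHxA. Asking for 50 or more, it was 600 µM for PFHxA, 120 for PFOA, 40 for PFNA, 200 for PFHxS and 1.2 µM for PFOS.

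Against each chemical's own lowest concentration, shares at the highest concentration were 0% for PFBA, 2.73% for PFHxA, 0.377% for PFOA, 13.9% for PFNA and 0.189% for PFDA, and the log2 changes that turned sign were 0.067 for gpx1a (PFHxA), 0.12 for ptgs2b (PFOA), 0.11 for gngt1 (PFOA) and 0.21 for lyz (PFOA). As differences of changes from each chemical's own lowest concentration, shares that differed were 0.471% between PFBA and PFBS, 0.628% between PFHxA and PFHxS, 18.7% between PFOA and PFOS, 0.660% between PFBA and PFHxA, 0.0628% between PFOA and PFDA and 0.0943% between PFOS and PFDA, and the log2 changes that turned sign were −0.33 for ncaph (PFHxA minus PFHxS), 1.15 for polr1b (PFOA minus PFOS), −0.16 for hsp90aa1.2 (PFOA minus PFDA), −1.07 for LOC101882968 (PFOS minus PFDA) and 0.060 for per2 (PFOS minus PFDA). Against control_ottawa, the log2 change that turned sign was 0.10 for mdm2 (PFOS). With the fish origin score as a covariate, PFOS shares were 4.18% at the highest and 10.7% at any concentration. There, its lowest concentration with calls was 12 µM, and the log2 change that turned sign was 0.40 for mhc1uba. With the background score as a covariate, shares at the highest concentration were 0.377% for PFBA and 7.82% for PFHxA, and shares at any concentration were 0.0314% for PFBA and 0.723% for PFBS. There, the lowest concentration with calls was 600 µM for PFHxA, and the log2 change that turned sign was 0.37 for gpx1a (PFHxA). Without probes that differ between the DMSO groups, the lowest concentration with calls was 200 µM for PFHxS. Without libraries far from their group, shares at the highest concentration were 0.220% for PFBA and 3.55% for PFOA, and 0.534% for PFBA at any. There, the lowest concentration with calls was 600 µM for PFHxA.

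Ranges that moved without each library in turn (at the highest concentration, of that group or its controls) follow. At the highest concentration, PFBA ranged from 0.0314% to 0.251%, PFOA from 1.26% to 3.05% (without control_mixed replicates 1 and 4), PFDA from 0.189% to 0.628% (without control_mixed replicates 2 and 3) and PFBS from 0.377% (without PFBS 600 µM replicate 2) to 0.848% (without control_ottawa replicate 3). At any concentration, PFBA ranged from 0.0628% to 0.534% (without control_ottawa replicate 2 and PFBA 250 µM replicate 1) and PFHxA from 4.68% to 12.4% (without PFHxA 600 µM replicate 3 and 200 µM replicate 1). There, PFOA ranged from 1.13% to 2.95% (without control_mixed replicate 2 and PFOA 4 µM replicate 1), PFDA from 0.283% to 1.16% (without control_mixed replicates 1 and 3), PFBS from 0.723% to 4.34% (without PFBS 600 µM replicate 3 and 80 µM replicate 2) and PFDS from 2.67% to 7.04% (without PFDS 6 µM replicate 4 and 2 µM replicate 4). Between chemicals, PFOA and PFDA ranged from 0.126% to 0.346%, PFOS and PFDA from 6.82% to 13.04%, PFNA and PFOA from 1.41% to 2.51%, PFNA and PFHxA from 3.64% to 6.001% and PFNA and PFDA from 0% to 0.220%. The point of departure was 1.14 to 2.88 µM for PFHxA, 1.397 to 20.5 for PFBS and 13.7 to 33.6 µM for PFHxS. PFOS had 0.124 to 2.79 and PFDA (4 of 24 refits) 0.0146 to 0.0431 µM. The RNA integrity difference ranged from 0.285 to 0.425 for PFBA, 0.15 to 0.3 for PFHxA, −0.388 to −0.221 for PFNA and 0.183 to 0.325 for PFBS. For PFHxA, PFNA, PFHxS, PFOS and PFDS at the highest concentration, and for the other matched comparisons, no library moved the count by over 1.5 times.

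Groups share replicate numbers, but the numbers did not pair the pools: of 36 same-numbered pairs of exposed and control pools, 2 correlated above 0.1 (r from −0.188 to 0.153) and 7 exposed pools correlated best with their own number. Under the block 14 of 206 values of named genes lost the call and 0 turned sign. With the replicate number as a block, the lowest concentrations with calls were 600 µM for PFHxA, 4 µM for PFNA and 60 µM for PFHxS, and the point of departure was 0.948 µM for PFNA. There, the share at the highest concentration was 0.314% for PFDA, and shares at any concentration were 0.283% for PFDA and 0.597% for PFBS. There, shares that differed were 0.0943% between PFBA and PFBS, 5.50% between PFNA and PFOA, 10.18% between PFNA and PFHxA and 2.17% between PFNA and PFDA.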

Other observations

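The counts over other splits were planned. Libraries were regrouped in 100 ways with the same group sizes, the real one included, or 35 where no more exist (PFDA and PFDS at the highest concentration, and pairs of 4 pools against 4). At the highest concentration 1 split, the real one, gave as many calls for PFHxA (558 genes, highest other 337), PFOA (69, 26), PFNA (942, 637), PFHxS (573, 320), PFOS (743, 450), PFDA (16, 8) and PFDS (277, 0), and 2 did for PFBS (24, 52), all shares of splits under 0.05. For PFBA 6 splits did (4, 31), a share of 0.05 or more. Shares here and below were not adjusted over the many tests, so they do not by themselves exclude chance. At any concentration, the share was under 0.05 for PFHxA (2 splits, 270 genes, highest other 290), PFOA (1, 65, 31), PFNA (1, 696, 70), PFDA (3, 14, 40), PFHxS (1, 524, 71), PFOS (1, 632, 15) and PFDS (1, 196, 3). It was also under 0.05 for PFBS (2, 40, with the highest other 3.55 times as many), but not for PFBA (5, 5, 81). For the count of gene lists, chance is excluded for PFBA (2; 4, 4), PFOA (3; 7, 7), PFNA (3; 13, 14) and PFDS (1; 11, 9), and not for PFHxA (6; 11, 12), PFDA (15; 3, 6), PFBS (6; 6, 8), PFHxS (7; 10, 11) or PFOS (13; 7, 8). Between chemicals, 1 split gave as many for PFHxA and PFHxS (456, 8), PFOA and PFOS (1007, 321), PFBA and PFHxA (305, 3), PFOA and PFDA (10, 1), PFOS and PFDA (380, 244), PFNA and PFOA (77, 35) and PFNA and PFHxA (182, 40), again shares under 0.05. For PFNA and PFDA at 4 µM 9 splits did (3, 27), and chance is not excluded. For PFBA and PFBS at 600 µM the real count was 0. All 35 splits gave as many by construction (highest other 1), which says nothing of chance. Some splits called several times the real count, for PFBA, PFBS and PFDA and for PFNA against PFDA. Background scores split control_ottawa (0.042 to 0.135, 0.9 to 1.015), a structure the groups do not follow. No other was tested.

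Water libraries held 5.65% of the median count of embryo libraries, with counts at 2516 probes (median) against 3012, and their mean log2 CPM followed the embryo mean across probes (r = 0.909; probes are not independent replicates). The reference RNA kinds differed in 1942 of 2504 probes, and within them 34 of 2687 probes differed between plates (296 with an unadjusted p under 0.05). Of 3 measured ionocyte genes, 2 were higher with PFNA (3 adjusted over the list alone), 2 with PFHxS and 1 each with PFHxA, PFOS and PFDS.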
